A study of Homo sapiens with 6 samples.

How the data were processed

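H3K4me3, the trimethyl mark on lysine 4 of histone H3 found at active promoters, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in BE(2)-C cells. BE(2)-C is an established human neuroblastoma cell line with an amplified MYCN gene. Cells had received a control siRNA or an siRNA against WDR5, a subunit of H3K4 methyltransferase complexes, for 24 hours per the labels. The 6 libraries comprise 2 H3K4me3, 2 IgG and 2 input libraries, with 1 of each kind per siRNA, so no group holds replicates. Each library was assigned to its group by its title, its source and its antibody.

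Per the submitters' processing notes, the tools were BWA 0.7.12 and bedtools and the genome build was hg19, with no role stated for either tool. The peak caller, its threshold and the control library used for calling are not given in the sources used here. Of the 3 files the authors deposited, 1 holds a pair of gene name lists, the names with an H3K4me3 peak within 1 kb either side of the transcription start site (TSS) in each H3K4me3 library, per the file headers. The other 2 are promoter tables, for N-Myc-binding and N-Myc-non-binding promoters. The deposited tables give a TSS interval 1 bp wide and a gene name per promoter, and no other column. The authors named these tables as quantifying H3K4me3, so their order may come from values that the tables used here do not hold. How N-Myc binding was decided is not given in the sources used here, and the N-Myc ChIP data were not analysed here. The second coordinate of each interval was taken as the 1-based TSS position on hg19.

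The deposited columns hold names and positions in no measured unit, so the depth behind a peak call is unknown and no call carries a height, p-value or read number. The design fixed before the data were examined assumed an H3K4me3 level per promoter. Its log2 ratios, fold thresholds, level matching, pseudocounts, scalings and background subtraction could not be computed, and peak calls were compared in their place. IgG and input values were not used here.

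Names were reduced to distinct names per list. Each name was classed as listed in both libraries, in control siRNA only, in WDR5 siRNA only or in neither. A name in neither list can be a promoter without a peak or a gene that the authors' annotation gave another name. Promoters were joined to the peak lists by gene name, and each gene name had at most 1 row in the promoter tables. A peak at another TSS of the same gene can thus count for the listed promoter. The control list held 92 names more than once. Of 16500 names in the files, 15689 matched a RefSeq symbol or an unambiguous synonym of the GRCh38.p14 annotation, which was used for names only.

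With 1 library per siRNA no test across replicates exists and no p-value is given. Shares carry exact (Clopper-Pearson) 95% intervals over genes. These treat genes as independent draws and cover neither replicate nor library error. To describe whether a gene group stood apart, its number of control-only names was placed among 10000 random lists of the same size drawn from all control names. Ties count as their midpoint in the percentile. Percentiles were read against limits of 2.5 and 97.5, and lists with fewer than 5 control names were given none. For gene lists the random range is the central 95% of random lists. For the promoter classes it is the full range. Random lists could not be matched on H3K4me3 level, so matching on N-Myc promoter class was run as an alternative. Data were simulated with 13618 names and list members drawn independently. Of lists of 20 genes with a 3-fold raised share, 81.8% passed the limits, and 2.6% of lists at the overall share did. For lists with no control-only member the count was fixed, so only the random lists varied between repeats. Such lists passed in 100.0% of repeats with 30 genes and 23.4% with 20 genes. These values show only whether a list of that size can reach the lower limit.

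The 18 gene lists were fixed before the data were examined. The fixed rule for named genes covered the always-named genes WDR5, MYCN, MYC, MDM2, CCNE1, ODC1, NCL, ACTB and GAPDH and the members of 3 lists (MYC network, MYCN amplicon neighbours, H3K4 methyltransferase complexes). Its parts that rank promoters by ratio could not be applied. In the other lists, members listed in only 1 library are named, together with examples listed in both. Genes named outside the lists were chosen after the values were seen. The alternatives planned beforehand that could be run were restriction to names with a single row and removal of MYCN amplicon neighbours, and 7 further settings were added later. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.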

Results

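H3K4me3 peak calls near transcription start sites were compared between BE(2)-C neuroblastoma cells treated with control siRNA and with WDR5 siRNA. WDR5 binds the histone H3 tail and is a core subunit of the H3K4 methyltransferase complexes. N-Myc is the MYC-family transcription factor encoded by MYCN. The data were 1 list of genes with a peak per siRNA, from 1 H3K4me3 library each, and tables of 3254 N-Myc-binding and 6331 N-Myc-non-binding promoters. No level, read number or depth accompanied the lists, so each value below describes these libraries and has no replicate error.

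The first comparison asked how many promoters carried an H3K4me3 peak after WDR5 siRNA. Fewer genes were listed with WDR5 siRNA than with control siRNA. The control library listed 13618 distinct names (13712 rows) and the WDR5 siRNA library listed 11870 (11942 rows), a ratio of 0.872. Names listed in both numbered 11773, or 86.5% of the control names. A further 1845 names, 13.5% of the control names (95% interval over genes 13.0 to 14.1%), were listed only with control siRNA. Only 97 names, 0.817% of the WDR5 siRNA names, were listed only with WDR5 siRNA. Control-only names thus outnumbered WDR5-siRNA-only names 19.0 to 1. The number of peaks called also depends on sequencing depth and immunoprecipitation yield, which are unknown here.

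Of the genes tied to the study's question, WDR5 itself was listed in both libraries. MYCN (TSS at chromosome 2, position 16080683) was an N-Myc-binding promoter listed in both. MDM2, the ubiquitin ligase that restrains p53, CCNE1, which encodes cyclin E1, ODC1, which encodes the first enzyme of polyamine synthesis, and NCL, which encodes nucleolin, were N-Myc-binding promoters listed in both. ACTB and GAPDH were listed in both. MYC (chromosome 8, position 128748315), an N-Myc-non-binding promoter, was listed only with control siRNA.

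The second comparison asked whether N-Myc-binding promoters differed from non-binding ones. N-Myc-binding promoters carried a peak more often in either library, and a smaller share of their control peaks was missing from the WDR5 siRNA list. With control siRNA, a peak was listed for the gene of 3087 of 3254 N-Myc-binding promoters (94.9%, interval 94.1 to 95.6%). Among non-binding promoters the number was 3675 of 6331 (58.0%, interval 56.8 to 59.3%). With WDR5 siRNA the numbers were 2962 (91.0%, interval 90.0 to 92.0%) and 3053 (48.2%, interval 47.0 to 49.5%). Among promoters with a control peak, 129 N-Myc-binding ones were control-only (4.18%, interval 3.50 to 4.95%), against 656 non-binding ones (17.9%, interval 16.6 to 19.1%). The difference was 13.7 percentage points (interval 12.2 to 15.1), a 4.27-fold ratio. With all promoters of each table as the denominator, an alternative chosen after the data were seen, the difference was 6.40 percentage points. These shares do not show that N-Myc-binding promoters were less affected. On a probit scale, which assumes normally distributed log levels of equal spread, the share with a peak moved by 0.290 units in the binding class. In the non-binding class it moved by 0.248.

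Random lists of the size of the N-Myc-binding group held 362 to 476 control-only names, so the observed 129 lay below all 10000 of them. The 656 among non-binding promoters lay above the random range of 419 to 559. The 6856 control names in neither promoter table had 1060 control-only names (15.5%). WDR5-siRNA-only names were few in both classes. They numbered 4 of 167 N-Myc-binding promoters without a control peak (2.40%, interval 0.656 to 6.02%) and 34 of 2656 non-binding ones (1.28%, interval 0.888 to 1.78%), and these intervals overlapped. How the classes were defined relative to H3K4me3 is not given in the sources used here, and the classes could not be matched on H3K4me3 level.

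**Figure D1:**
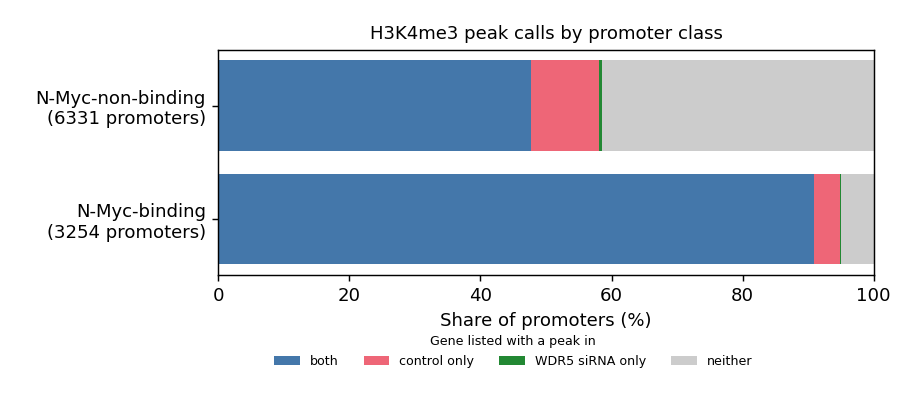
Share of promoters (%, x axis) in the N-Myc-binding and N-Myc-non-binding tables whose gene was listed with an H3K4me3 peak in both libraries, in control siRNA only, in WDR5 siRNA only or in neither. Control-only promoters numbered 129 of 3254 in the binding table and 656 of 6331 in the non-binding table.

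Genes of ribosome production, DNA replication and the p53 response were mostly listed in both libraries. A name listed in both has a call in each library, which does not show that its H3K4me3 level was unchanged. All 76 ribosomal protein genes with a control peak remained listed with WDR5 siRNA (random range 5 to 16 control-only, percentile 0.00). Examples were RPL7A, RPL24 and RPL35A. All 29 ribosome biogenesis genes with a control peak, such as NOP58, WDR12 and POLR1B, were also listed in both (random range 1 to 8, percentile 0.60). Of 40 DNA replication and cell cycle genes, 39 were listed in both, among them MCM2, CDC6 and CCNE1. The exception was TK1, which encodes thymidine kinase (random range 2 to 10, percentile 1.28). All 24 p53 target genes with a control peak were listed in both, with MDM2, BAX and BBC3 among them (percentile 1.51, although the central random range of 0 to 7 includes 0). Against random lists matched on N-Myc promoter class, the DNA replication list stood at percentile 8.14 and the p53 list at 4.68, both within the limits. The matched range was closer to the observed counts for ribosomal proteins (1 to 10, percentile 0.195) and ribosome biogenesis genes (1 to 7, percentile 1.1). Both of these lists stayed below the lower limit.

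MYC target genes, a list fixed from general knowledge, had 28 members with a control peak, and 26 were listed in both. The control-only members were TERT (chromosome 5, position 1295162), the catalytic subunit of telomerase, and LDHA (chromosome 11, position 18417813), a lactate dehydrogenase subunit. Both were N-Myc-binding promoters. The list lay within the random range of 1 to 8 (percentile 16.7). In the MYC network, 17 of 18 genes were listed in both, namely MYCN, MYCL1, MAX, MXD1, MXD3, MXD4, MXI1, MNT, MGA, MLX, MLXIP, ZBTB17, TRRAP, KAT2A, KAT5, RUVBL1 and RUVBL2, and MYC was the exception (percentile 18.0). Of the genes around MYCN, which is amplified in this line, MYCNOS, DDX1 and NBAS were listed in both and FAM49A only with control siRNA (1 of 5 with MYCN included, percentile 66.9).

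The 18 H3K4 methyltransferase complex genes with a control peak were all listed in both (percentile 3.94, within the limits). They were WDR5, RBBP5, ASH2L, DPY30, KMT2A, KMT2B, KMT2C, SETD1A, SETD1B, CXXC1, MEN1, HCFC1, HCFC2, WDR82, PAXIP1, NCOA6, PSIP1 and PAGR1. KMT2D was in neither list. All 6 H3K4 demethylase genes with a control peak were listed in both (percentile 20.8). The same held for 20 aminoacyl-tRNA synthetase genes (percentile 2.65) and 13 housekeeping genes (percentile 7.63). Apoptosis regulators had 17 of 18 in both, with BIK, a pro-apoptotic BCL2-family gene, control-only (percentile 17.5).

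HOX genes, the homeodomain regulators of body axis patterning, were control-only more often than random lists. Of 20 HOX genes with a control peak, 8 were control-only (40.0%, random range 0 to 6, percentile 99.8). These were HOXA10, HOXA11, HOXB9, HOXB13, HOXC5, HOXC10, HOXC11 and HOXD12. The 12 listed in both lay mainly in the HOXC and HOXD clusters, such as HOXC9, HOXC13, HOXD9 and HOXD13, with HOXA13 the only one from HOXA and none from HOXB. A further 19 HOX genes, among them HOXB2 to HOXB8, were in neither list. The random lists drew names independently, whereas HOX genes lie in clusters and control-only names tended to be neighbours. The HOX percentile ignores this and may be too extreme.

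Genes of the mesenchymal neuroblastoma state and of fibroblasts also stood above the random range. Of 19 with a control peak, 7 were control-only (36.8%, random range 0 to 6, percentile 99.5). They were YAP1 and WWTR1, which encode the YAP and TAZ co-activators, CYR61, FOSL1, an AP-1 subunit, NOTCH3, and the matrix genes FN1 and COL1A1. CTGF, VIM, CD44, SNAI2 and TWIST1 were listed in both. FOSL1, FN1 and NOTCH3 were N-Myc-binding promoters. A further 9 of the 28 members were in neither list. Random lists could not be matched on H3K4me3 level. An excess that comes from weak control peaks near the detection threshold therefore stays open, for this list and for HOX genes.

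Adrenergic neuroblastoma genes showed no excess as a list, with 5 of 27 control-only (18.5%, random range 1 to 7, percentile 77.4). The 5 included TH (chromosome 11, position 2193035), DDC (chromosome 7, position 50628768) and DBH (chromosome 9, position 136501485). Their products act in sequence in catecholamine synthesis, a grouping made after the calls were seen and not tested. The other 2 control-only members were SOX11 and LMO1. Of the same list, SLC18A2, SLC6A2, CHGA and CHGB were listed in both and SLC18A1 in neither. Lineage regulators such as PHOX2A, HAND2, GATA3 and ISL1 were listed in both, as were ALK and RET. EYA1 was listed only with WDR5 siRNA, and no other member of the 18 lists was.

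Markers of other cell types were mostly unlisted. Of 22 blood, epithelial, liver and muscle markers, 21 were in neither list, and KRT18 was control-only. Of 8 Schwann cell markers, 3 were listed in both and 5, including SOX10, in neither. Replication-dependent histone genes had 47 of 57 names in neither list, which can reflect the annotation as well as peaks. Of the 10 with a control peak, HIST1H1C was control-only (percentile 42.2). Over the 16 lists with a percentile, 2 lay above and 4 below the limits. Of simulated lists at the overall share, 2.6% (20 genes) to 4.8% (80 genes) lay beyond them, and several of the shorter lists cannot pass the lower limit. The simulation drew members independently, so a rate of this size was built in. Real control-only names were neighbours more often than when shuffled (401 consecutive pairs against a mean of 250). The rate is therefore unknown for lists of neighbouring genes such as HOX.

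**Figure D2:**
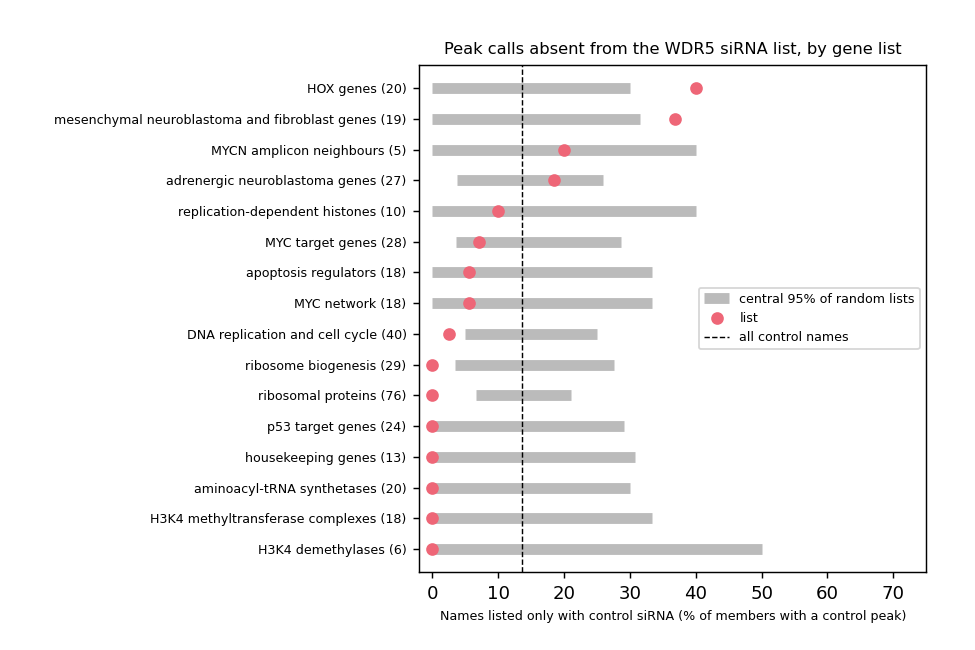
Share of list members with a control peak that were listed only with control siRNA (%, x axis) for 16 gene lists, with the number of members with a control peak in brackets. Points are the lists, grey bars the central 95% of 10000 random lists of the same size, and the dashed line the 13.5% of all control names; HOX genes (40.0%) and mesenchymal and fibroblast genes (36.8%) lie right of their bars.

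The promoter tables, which the authors named as quantifying H3K4me3 but which hold no values here, carry an order of rows that their headers do not explain, and the peak calls followed it. In the N-Myc-binding table the median row position was 45.6% of the table length for promoters listed in both libraries. It was 90.3% for control-only, 97.0% for unlisted and 99.8% for WDR5-siRNA-only promoters. In the non-binding table the corresponding medians were 23.9%, 51.5%, 78.4% and 98.4%. MYCN held row 1 of the N-Myc-binding table, RPL7A row 2 and NCL row 13, while MDM2 held row 1201, ODC1 row 1662 and CCNE1 row 2523. The non-binding table began with TLE1, RIMS2, DUSP4 and INSM2.

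**Figure D3:**
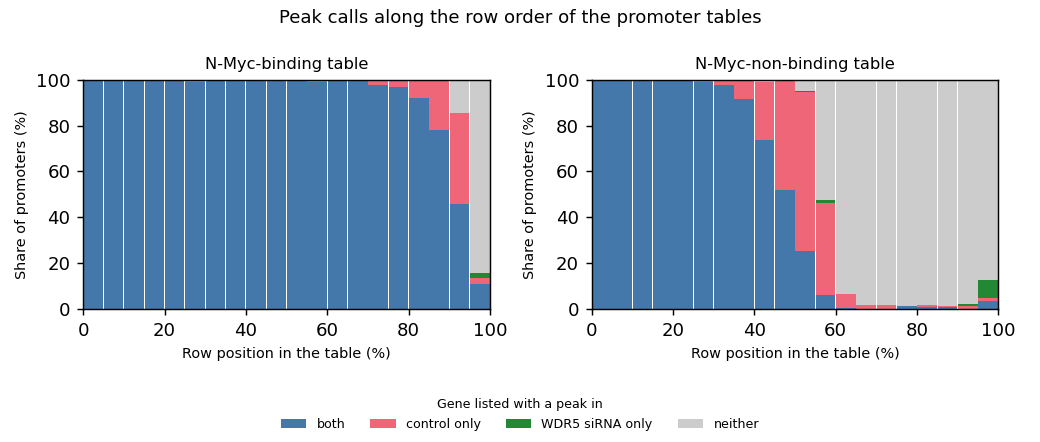
Share of promoters (%, y axis) by peak call along the rows of each promoter table, in 20 bins of row position (%, x axis, 0 is the first row). Control-only promoters lie where promoters listed in both give way to unlisted ones, and 24 of the 34 WDR5-siRNA-only promoters of the non-binding table lie in its last 5% of rows.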

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

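All tests in this part were chosen after the row order had been seen. The row order of the promoter tables is information that no comparison of peak numbers used. Names listed only with WDR5 siRNA had a median position of 99.78% of the table length in the N-Myc-binding table (4 promoters) and 98.39% in the non-binding table (34 promoters). No promoter came with a value, so what the order stands for is a hypothesis.

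A sort from high to low control H3K4me3 level would place WDR5-siRNA-only promoters no later than unlisted ones. In the non-binding table they were later in 79.98% of pairs (bootstrap interval 67.5 to 90.8%), which argues against that sort. A sort by the ratio of control to WDR5 siRNA, from high to low, would put control-only promoters ahead of those listed in both, yet they came later in 94.19% of pairs (interval 93.4 to 94.9%). From low to high it would put WDR5-siRNA-only promoters ahead of control-only ones, yet they came later in 97.78% of pairs (interval 95.7 to 99.3%). A sort by the drop in level from control to WDR5 siRNA stays open. The medians ran from both to control-only, unlisted and WDR5-siRNA-only in 6 of 6 steps, but they had been seen beforehand, and such a sort need not place promoters listed in both ahead of control-only ones. No biological explanation was tested. The last rows held RPL35A, IQCG and RPL24 in the N-Myc-binding table and TNRC6B and DDR2 in the non-binding table, all listed in both libraries.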

How the results depend on the processing

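With 1 library per siRNA no replicate could be left out, and alternatives listed beforehand on pseudocounts, low-value filters, scalings, fold thresholds, level matching, summed values, highest promoters and background could not be run, because the tables hold no levels. Each gene had 1 promoter, so using all promoters of a gene changed nothing. Restriction to names with a single row (listed beforehand) left 1837 control-only and 96 WDR5-siRNA-only names, and leaving out the MYCN amplicon neighbours (listed beforehand) left the class difference at 13.7 percentage points. The other settings were chosen after the data were seen. Counting rows as deposited or dropping accession-style, LOC and numeric names left the 3 peak list values within 1.5 times or within their intervals over genes, and keeping promoters with no other listed TSS within 2 kb or on autosomes did so for the 3 promoter class values. With all promoters of each table as the denominator, the control-only share was 10.4% for non-binding promoters and the difference 6.40 percentage points, because promoters without a control peak, more common in that table, enter the denominator. Of 16 gene list percentiles, matching random lists on promoter class moved 2 within the limits (DNA replication and cell cycle to 8.14, p53 targets to 4.68), left HOX genes at 99.2 and mesenchymal genes at 99.9, and the other backgrounds moved none across. Depth is unknown, so a missing name is a missing call and does not show absence of H3K4me3. A name listed in both can likewise differ in level between the libraries.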

Other observations

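Beyond the fixed lists, a scan of 80 symbol families with at least 15 control names, chosen after the data were seen, showed which promoters were control-only most often. Collagen genes had the highest share, with 8 of 19 names starting COL control-only (42.1%), among them COL1A1, COL7A1, COL14A1 and the antisense name COL18A1-AS2. In 4.81% of 10000 shuffles of the calls some family stood as far above chance for its size. Next by share came ADAMTS (6 of 15), CYP (6 of 15), ALDH (6 of 17), SPATA (5 of 16) and GPR names (12 of 40), but for each of these at least 16.6% of shuffles held a family as extreme. At the other end, 31 of 451 ZNF zinc finger names were control-only (6.87%), farther below chance for its size than any family in the 10000 shuffles, and 0 of 41 RPS names were (3.91% of shuffles had a family as extreme). RPL names (1 of 53, 7.35% of shuffles) and EIF names (1 of 52, 8.84% of shuffles) were also rarely control-only. The shuffles treated names as independent, whereas control-only names tended to be neighbours. For families whose genes lie in clusters, the shares of shuffles may therefore be too small. Names of non-coding or uncharacterised transcripts were control-only more often than the 13.5% of all names, with 19 of 70 LINC names (27.1%), 71 of 310 LOC names (22.9%) and 96 of 421 accession-style names (22.8%). Antisense names were at 12.9% (34 of 263).

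The control list follows genome order, since 6734 of 6737 consecutive pairs on one chromosome with known positions rose in position. There were 4 runs of at least 5 consecutive control-only names. The longest, of 6, held FAM27B among accession-style and LOC names. Of the 3 runs of 5, one was the metallothionein group MT2A, MT1M, MT1DP, MT1F and MT1X, and the others ran from MYCBPAP to ABCC3 and from TRIL to PRR15, without an evident shared function. Of the 97 WDR5-siRNA-only names, 80 were neither accession-style, LOC nor numeric. They were of mixed kinds, such as MAP2, SEMA3A, LHX2, TLR4, APOBEC3B and OR1L3, and no group among them was tested.

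Of the tests in the paragraphs that follow, only the one on neighbours over 10 kb apart was written before its result was seen. For the lower control-only share among N-Myc-binding promoters, peaks shared between TSSs of the promoter tables are not enough. The difference was 14.02 percentage points (interval over genes 12.5 to 15.6) among promoters with no other listed TSS within 2 kb. That restriction kept 2668 of 3087 binding and 3502 of 3675 non-binding promoters with a control peak. It removed too few for the difference to disappear. The 6856 control names in neither promoter table have no position here, so peaks shared with those genes stay open. One shift of the detection threshold common to both classes is not argued against. On a probit scale, which assumes normally distributed log levels of equal spread, the share with a peak moved by 0.290 units in the binding class and 0.248 in the non-binding class, a difference of 0.042 (interval -0.0090 to 0.101). The peak calls are therefore consistent with a like shift in both classes, with the N-Myc-binding class starting farther above the threshold. A role of N-Myc binding itself stays open, as untested.

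Whether the excess of control-only over WDR5-siRNA-only names rests on weak peaks near the detection threshold stays open. In the N-Myc-binding table, control-only promoters lay later than those listed in both in 93.95% of pairs (interval 91.9 to 95.7%) and later than unlisted ones in 3.33% (interval 1.40 to 5.88%). This decides nothing on peak strength, since the tables do not say whether row position follows an H3K4me3 level. Lower sequencing depth or ChIP yield of the WDR5 siRNA library cannot be told apart from an effect of the siRNA. The ratio of 19.02 control-only names per WDR5-siRNA-only name fits either, and 1 library per siRNA with no depth keeps it open.

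Over the whole control list, 401 consecutive pairs were both control-only, against a shuffled mean of 250 (range 200 to 299). Among neighbouring promoters of the promoter tables, shuffled within class, 124 pairs were both control-only against a mean of 95.9 (ratio 1.29, range 63 to 128, percentile 99.9). Among those more than 10 kb apart, 111 pairs were, against a mean of 90.6 (ratio 1.225, range 60 to 126, percentile 99.1). The count beyond 10 kb lay inside the full shuffled range. That was the outcome set for this test if a peak shared by neighbouring TSSs were the source. Yet the count stood at percentile 99.1 of the shuffles, so the test does not decide. The ratios of 1.29 and 1.225 do not set near against far neighbours. Of the 6738 neighbouring pairs, 6320 lay more than 10 kb apart and entered both ratios. A listed name needs a peak within 1 kb of a TSS, so a shared peak would have to span most of such a distance. Whether a peak shared by the listed TSSs is the only source of the excess beyond 10 kb stays open. A peak at another TSS of either gene can count, so shared peaks are not excluded. A regional component was not tested directly.

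The peak lists hold 20 names that are bare numbers, and 2 of these were control-only. Read as spreadsheet day counts, 10 are 1 March and 10 are 1 September, so all 20 are dates of a form that spreadsheets make from MARCH and SEPT gene symbols. The lists hold 0 intact MARCH or SEPT symbols, which is consistent with gene names turned into dates by a spreadsheet. Only the month and day of each date were read, so calls for those genes were not assigned here.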
